A study of Homo sapiens with 2 samples.

How the data were processed

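Gene expression was profiled with single-colour arrays in U-2OS, an established human osteosarcoma cell line. The series holds 2 samples. One was transfected with a negative control siRNA and the other with an siRNA against GLI2, a zinc finger transcription factor of the hedgehog pathway. Both were treated for 48 h, and 100 ng of total RNA was biotin-labelled, per the labels' protocols. The platform record names the Affymetrix Human Gene 1.0 ST array, whose probe sets lie along the whole transcript. Each group has 1 array, so there is no replicate and no estimate of the spread between cultures. Whether an array holds RNA of 1 culture or of several pooled is not given in the sources used here. No p-value was computed, and all values below describe these 2 arrays.

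The deposited table gives 1 intensity per probe set and array on a linear scale, with 28869 probe sets in all. The linear scale was read from the values, which ran from 4.76 to 17626.3 on the negative siRNA array and from 4.86 to 18463.0 on the GLI2 siRNA array. The column medians were 92.6 and 91.4. MAS5 is the one tool named, per the submitters' processing notes. Its role and version, the background correction, the summarization and the scaling of the intensities are not given in the sources used here. This array type lacks the paired mismatch probes that MAS5 was built for, so the summarization behind each intensity, and with it behind each difference below, is uncertain. A total of 755 probe sets (2.62%) carried exactly the same value on both arrays. This held for 8.45% of the probe sets in the dimmest 10% and for 0.139% of those in the brightest 10%. For such a probe set the table holds no difference at all between the samples. Median-polish summaries of 2 arrays can give identical values, and whether they did here was not tested.

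Probe sets were named from the platform annotation, with symbols checked through Entrez identifiers in a RefSeq gene table for GRCh38.p14. Of the 28869 probe sets, 19310 had 1 gene symbol, 1752 had several and 7807 had none here. Of the 19310, 19279 matched the RefSeq table, no symbol changed, and 31 kept the symbol of the annotation. Probe sets with several symbols or none entered no gene result. The build behind the probe sets is not given in the sources used here, so no coordinates are reported. Gene order and the position of a small RNA inside another gene were taken from the RefSeq table.

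Intensities were transformed as log2(intensity + 16). The log2 difference was the GLI2 siRNA value minus the negative siRNA value, less the median difference of all probe sets with a gene symbol (-0.0086). Genes were counted as higher or lower by the sign of this difference. A gene with equal intensities on both arrays therefore has 0.0086 and counts as higher, as can one with a barely lower GLI2 siRNA intensity. Differences on this scale understate the change of dim genes. Level was the mean log2 value of the 2 arrays, and the level filter was the median level of the 19310 probe sets with 1 symbol, equal to an intensity of about 141. It kept 9655 probe sets. A probe set passed the size threshold at a 2-fold difference or more. Where a gene had several probe sets, the brightest stood for it, which gave 18377 genes.

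For 24 gene lists, the median log2 difference was set against 10000 random lists of the same size, drawn gene by gene from the same 20 level bins. A list was said to stand apart when its median lay below the 2.5th or above the 97.5th percentile. Chance alone would place about 1.2 of 24 unrelated lists there. Genes of a pathway vary together and 34 genes belong to more than 1 list, so random lists understate the spread of real ones. The lists held hedgehog components, reported GLI targets, cytosolic ribosomal proteins, extracellular proteolysis and invasion, epithelial-mesenchymal genes, integrins and focal adhesion, osteoblast differentiation, S phase, G2/M phase, p53 targets, apoptosis regulators, interferon-stimulated genes, inflammatory NF-kB targets, the unfolded protein and ATF4 response, cholesterol synthesis, hypoxia and glycolysis, TGF-beta targets, Wnt targets, Notch targets, the small RNA silencing machinery, housekeeping genes, and leukocyte, endothelial and epithelial markers.

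The genes named in the text followed a rule. GLI2 and RPS3 were always named, RPS3 because the series title names it. So were up to 12 genes per direction past the level filter and the size threshold, without small RNAs, olfactory receptors, histones and provisional symbols. Up to 4 members per list with the largest differences past the level filter could be named, and any hedgehog component. Other genes are marked as chosen after their values were seen. The lists, the rule, the thresholds and the alternative settings were fixed before the data were examined. The alternatives were no subtraction of the median, quantile normalization, a loess correction on level (span 0.3), pseudocounts of 1 and 64, other level filters and thresholds, the mean of a gene's probe sets, list members past the level filter only, and list means.

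The calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures used matplotlib 3.10.9. The calculations were tested on simulated arrays with the real levels of the 19310 probe sets and 200 planted differences. All planted 3-fold and 4-fold differences passed the threshold (100%), as did 44% of the 2-fold and 0% of the 1.5-fold ones, and 0 of 9455 unchanged probe sets did. Of 200 simulated unchanged lists of 40 genes, 5% fell outside the central 95% of random lists. Lists shifted by 0.15 were found in 100% of cases. The simulated differences were independent, normally distributed and of the same spread at all levels. The simulation therefore checks the calculations and gives no error rate for the real arrays, whose genes vary together and whose cultures may differ.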

Results

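The comparison asked which transcripts differ in U-2OS osteosarcoma cells after 48 h of GLI2 siRNA against a negative control siRNA, with 1 array per condition and no replicates. The arrays were close to each other. Their log2 levels correlated with r = 0.995 across 19310 probe sets, and summed intensity over all 28869 probe sets was 9309028 with negative siRNA and 9144418 with GLI2 siRNA. The 100 brightest probe sets took 9.55% and 9.33% of it. Past the level filter the log2 differences had an SD of 0.185 across probe sets, and 1% of them lay below -0.46 and 1% above 0.51. In 234 genes measured by 2 or more bright probe sets whose differences were not identical, the probe sets of 1 gene had a spread of 0.103 (SD per probe set). That spread covers the probes of these 2 arrays and not the variation between cultures. The 2 brightest probe sets of a gene disagreed by up to 0.82 in their log2 differences. GLI2 and RPS3 each rest on 1 probe set. Paired intensities are given with negative siRNA first and GLI2 siRNA second, and a signed value is the log2 difference, GLI2 siRNA minus negative siRNA. Counts of higher and lower genes go by the sign of that difference after median subtraction, so genes with equal intensities are counted as higher.

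GLI2, the target of the siRNA, was lower on the array labelled GLI2 siRNA by a modest amount. Its intensity was 296.3 with negative siRNA and 229.6 with GLI2 siRNA, 22.5% lower, a log2 difference of -0.34. Of 9261 genes past the level filter, 264 (GLI2 included) were as low or lower, as were 16 of the 500 other genes nearest to GLI2 in level. The single GLI2 probe set therefore sat toward the lower edge of the genes of its level and not outside them. GLI3, a second GLI transcription factor, had intensities of 891.2 and 995.2 (0.17), and GLI1, a transcriptional target and effector of the pathway, lay below the level filter at 83.2 and 86.7.

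Hedgehog pathway components as a list showed no shared direction. Of 30 measured genes, GLI2 included, 20 were higher and 10 lower with GLI2 siRNA, and 0 passed 1.5-fold. Their median of 0.041 lay at percentile 88.9 of random lists. The largest positive differences were those of PRKACA (0.42) and PRKAR1A (0.30), a catalytic and a regulatory subunit of protein kinase A. The receptor-associated transducer SMO had 0.24. PTCH1, the hedgehog receptor and a standard readout of GLI activity, had intensities of 506.9 and 514.1 (0.028). Reported GLI targets went both ways. SPP1, which encodes the secreted bone protein osteopontin, had intensities of 277.7 and 174.1 (-0.62), MYC 1402.5 and 1015.6 (-0.45), the transcription factor SNAI2 480.0 and 711.0 (0.56), and BMP4 702.9 and 961.3 (0.45). The median of the 31 measured targets was 0.065, at percentile 97.8, with 22 higher and 9 lower. Of 8 alternative settings the list stood apart only in the 1 with nothing subtracted, which shifts all lists equally and cannot change a percentile. In every other setting it lay inside the central 95%, down to percentile 94.8.

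RPS3, the ribosomal protein of the small subunit named in the series title, was 33.8% lower with GLI2 siRNA. Its intensities were 6510.3 and 4309.0, a log2 difference of -0.58 or a 1.5-fold lower level. Only 35 of 9261 genes (RPS3 included) were as low or lower, and none of the 500 other genes nearest in level was (0 of 500). Whether the submitters picked RPS3 from these same arrays is not given in the sources used here, so its rank is no independent evidence. Cytosolic ribosomal protein genes as a list were slightly lower, with 45 of 61 measured members below 0 and 16 above. Their median of -0.089 lay at percentile 0.05 of random lists. RPL27A was the lowest member at 581.7 and 361.1 (-0.66, the brighter of its 2 probe sets), followed by RPS3 and RPL26 (-0.29), while RPS13 was higher (0.26). Without RPS3 the median of the other 60 was -0.083 (percentile 0.13). Many ribosomal protein genes have near-identical processed pseudogenes, and 22 of the 83 listed had no probe set of a single symbol, so single values are uncertain. Another class, examined after the data were seen, moved the same way: small nucleolar RNAs (snoRNAs), short noncoding RNAs that guide ribosomal RNA modification, were lower in 74 of 80 cases past the level filter, with a median of -0.29. So were 17 of 20 small nuclear RNAs at all levels (median -0.10, percentile 0.13) and 16 of 23 short RNAs other than snoRNAs past the level filter (median -0.076, percentile 2.45), sets that overlap. The snoRNAs include SNORD15B (-0.47) and SNORD15A (-0.075), encoded within RPS3.

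**Figure D1:**
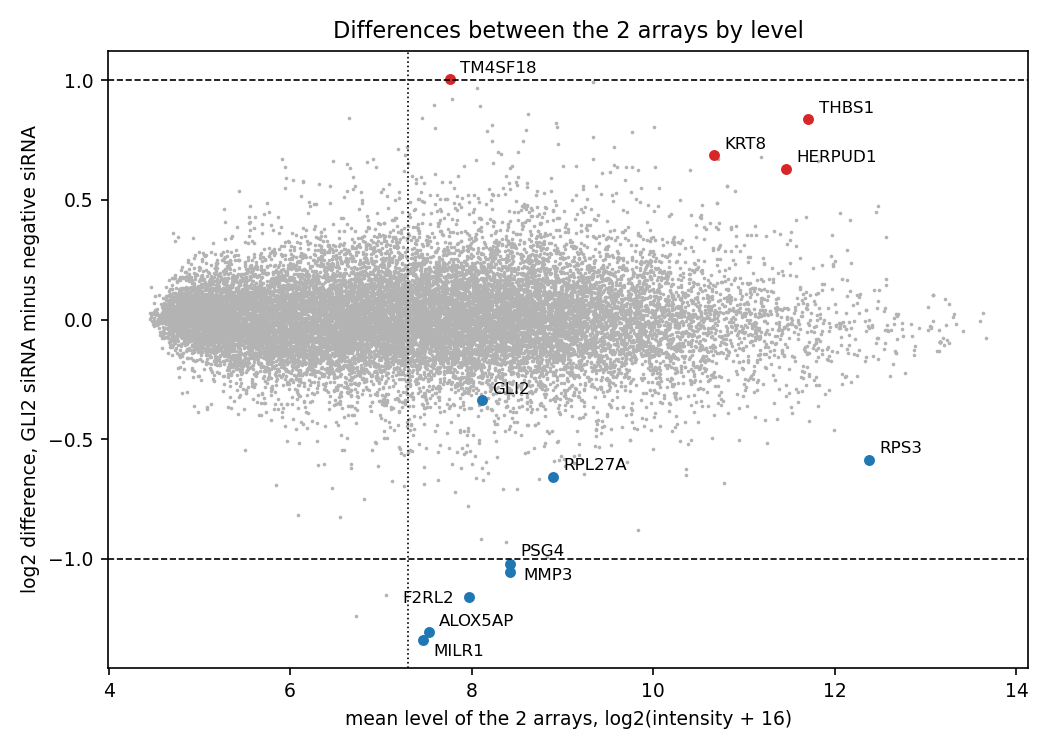
Each grey point is 1 of 19310 probe sets, with the mean level of the 2 arrays as log2(intensity + 16) on the x axis and the log2 difference, GLI2 siRNA minus negative siRNA, on the y axis; the dotted line marks the level filter and the dashed lines a 2-fold difference. Named points are higher (red) or lower (blue) with GLI2 siRNA: GLI2 (-0.34) lies at the lower edge of the cloud, RPS3 (-0.58) below the 500 genes nearest to it in level, and 5 genes past the filter lie below -1.

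Few genes differed by 2-fold. Of 9655 probe sets past the level filter, 6 passed this size threshold, 5 of them lower with GLI2 siRNA and 1 higher. The lower ones were MILR1, a mast cell immunoglobulin-like receptor (264.9 and 94.4, -1.34), ALOX5AP, which activates 5-lipoxygenase in leukotriene synthesis (274.4 and 100.8, -1.31), F2RL2, a thrombin receptor (361.2 and 151.8, -1.16), MMP3, the matrix metalloproteinase stromelysin (481.2 and 221.9, -1.05), and PSG4, a pregnancy-specific glycoprotein (472.4 and 223.0, -1.02). PSG4 belongs to a family of near-identical genes, so its signal may include relatives. The higher one was TM4SF18, a tetraspanning membrane protein (137.4 and 290.4, 1.01). At a 1.5-fold threshold 56 probe sets were higher and 35 lower, and at 3-fold none was (0 of 9655). The count of 6 moves with the pseudocount, and at a pseudocount of 64 only 2 lower probe sets passed 2-fold.

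Genes of matrix breakdown and invasion, the process the series title names, went both ways around 0. Of 45 measured genes 22 were higher and 23 lower, with a median of -0.0063 at percentile 47.3. Besides MMP3, the matrix glycoprotein TNC had intensities of 1218.0 and 826.3 (-0.54). The membrane-anchored protease MMP24 (0.57) and the protease inhibitor TIMP3 (0.46) were higher. The list pools proteases with their inhibitors, so a median near 0 does not show that invasion genes were unchanged. Chosen after their values were seen, ADAM12 (-0.34), ADAM17 (-0.30), ADAM10 (-0.27), ADAM15 (-0.23) and ADAM9 (-0.20) were lower. ADAM19 (0.27) and the inhibitor TIMP2 (0.39) were higher. The integrin and focal adhesion list had a median of 0.0061 (percentile 61.0). Its largest member was ITGB4, the laminin-binding integrin beta subunit, at 263.0 and 416.5 (0.64), followed by ITGB8 (0.34). Epithelial-mesenchymal genes stood apart, with 16 of 23 higher and a median of 0.083 (percentile 98.9). The list's leading members were epithelial as well as mesenchymal: the keratins KRT8 (1275.0 and 2048.8, 0.69) and KRT18 (0.35), SNAI2 (0.56) and fibronectin, FN1 (4075.3 and 4956.0, 0.29). Osteoblast genes had a median of 0.045 (percentile 91.6), with SPP1 at -0.62, BMP4 at 0.45 and BMP7 at 0.21.

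Of the 24 lists, 9 stood apart from random lists, 8 above and 1 below, where about 1.2 would be expected by chance. That figure assumes unrelated lists of genes that vary independently, which these are not. Cell cycle genes were shifted upward together by small amounts. Of 51 G2/M genes 43 were higher and 8 lower with GLI2 siRNA, and their median of 0.14 lay above all 10000 random lists. None reached 1.5-fold (0 of 51). The mitotic topoisomerase TOP2A had intensities of 857.2 and 1076.3 (0.33), the tubulin TUBB4B 2593.5 and 3249.6 (0.33), CDCA3 580.0 and 710.1 (0.29) and the ubiquitin-conjugating enzyme UBE2C 312.5 and 380.3 (0.28). S phase genes had a median of 0.093 (percentile 99.8), with 29 of 40 higher. They included the polymerase subunit POLA1 (0.49), the replication factor GINS2 (0.37) and the ribonucleotide reductase subunit RRM2 (0.36), while the histone mRNA binding protein SLBP was lower (-0.35). CCND1, a Wnt list member that drives G1 progression, had 0.25.

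**Figure D2:**
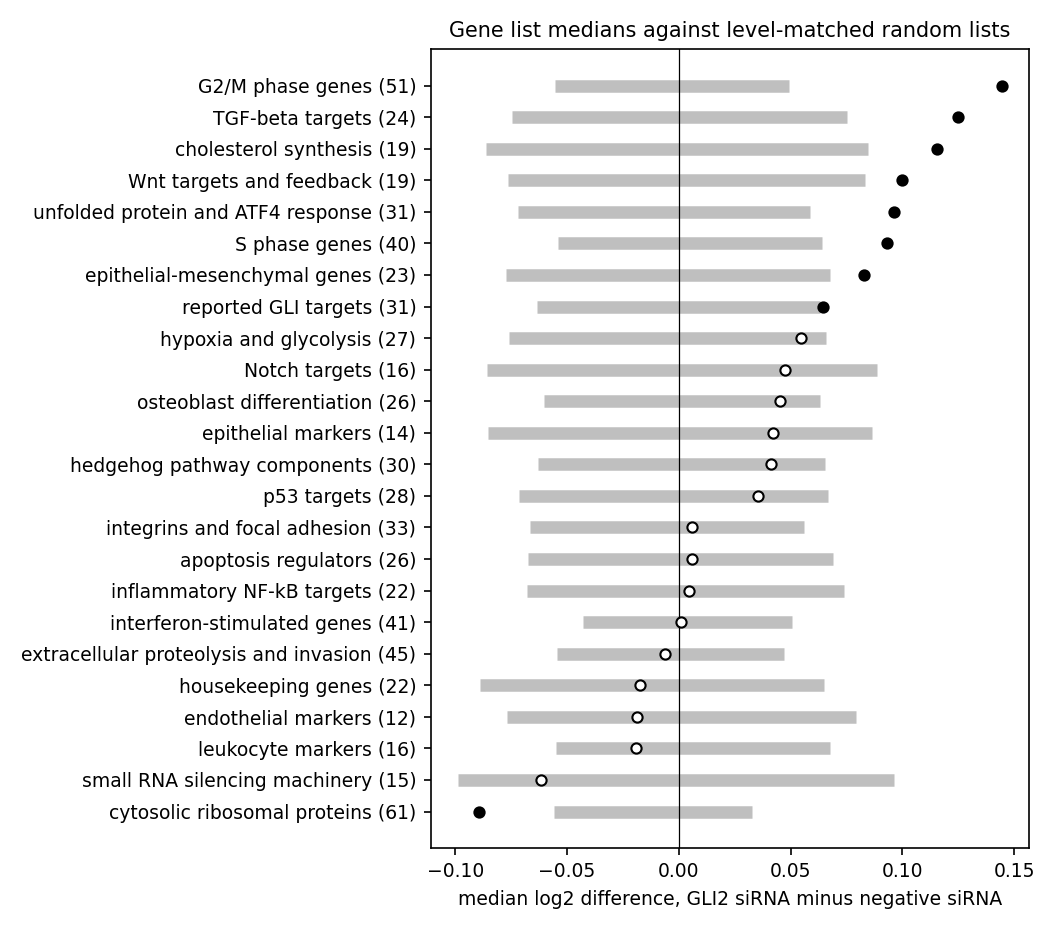
Each row is 1 of 24 gene lists with its number of measured genes; the point is the list's median log2 difference, GLI2 siRNA minus negative siRNA, and the grey bar the central 95% of 10000 level-matched random lists. Filled points are the 9 lists outside their bar, of which the ribosomal proteins (-0.089) lie below and 8 lists lie above, led by G2/M phase genes (0.14).

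Lists of the TGF-beta response and of the endoplasmic reticulum stress response had medians above random lists, with members in both directions. THBS1, which encodes the matrix protein thrombospondin-1, had intensities of 2491.8 and 4438.0 (0.84), the transcriptional regulator ID1 230.5 and 382.5 (0.70), the TGF-beta feedback inhibitor PMEPA1 1321.8 and 2103.8 (0.67), and BHLHE40 821.1 and 1143.2 (0.48). Of 24 measured TGF-beta targets 15 were higher and 9 lower, and the median was 0.12 (percentile 99.9), with 3 members past 1.5-fold. In the unfolded protein and ATF4 list, 19 of 31 genes were higher and 12 lower, and the median was 0.096 (percentile 99.9). Its leading members were HERPUD1, which acts in degradation from the endoplasmic reticulum (2255.5 and 3480.4, 0.63), SESN2 (0.53), DDIT4 (0.52) and the chaperone cofactor SDF2L1 (0.50). Its chaperones and folding factors went both ways. Chosen after their values were seen, HSP90B1 (-0.22), PDIA6 (-0.17), CALR (-0.13), HYOU1 (-0.10), PDIA4 (-0.096) and CRELD2 (-0.033) were lower. On the higher side were MANF (0.44), DNAJC3 (0.38), HSPA5 (0.17) and DNAJB9 (0.17). Cholesterol synthesis genes were higher in 13 of 19 cases, with a median of 0.12 (percentile 99.5). HMGCS1, an early enzyme of the mevalonate pathway, had 0.40, ACAT2 0.39, MVD 0.33 and FDPS 0.31. The Wnt list had a median of 0.0997 (percentile 99.2). AXIN2, its standard feedback target, had 0.32, MYC was lower at -0.45, and the list no longer stood apart when restricted to the 9 members past the level filter (percentile 93.7).

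The remaining lists lay within the central 95% of random lists in the main setting. Notch targets had a median of 0.047 (percentile 85.8), with MAML2 (0.45) and the ligand JAG1 (0.41) highest. Of the 11 members past the level filter 9 were higher, and restricted to those the median was 0.16 (percentile 99.3). The hypoxia and glycolysis list had 0.055 (percentile 95.3, and 97.6 under quantile normalization, where it stood apart), with the glycolytic enzymes GPI at 0.44 and HK2 at -0.43. The p53 targets had 0.035 (percentile 85.2) and apoptosis regulators 0.0058 (percentile 57.2), among them the survival factor BCL2 at -0.33. Interferon-stimulated genes, which respond to double-stranded RNA, had 0.0012 (percentile 44.9), and their largest difference past the level filter was that of IFI6 (-0.25). Only 11 of the 41 measured passed the filter, 4 higher and 7 lower. Both samples received an siRNA, so a response shared by them would not show here. Inflammatory NF-kB targets had 0.0047 (percentile 52.9) over 22 genes. Of the 12 past the level filter 8 were lower, led by the feedback inhibitors TNFAIP3 (-0.69) and NFKBIA (-0.39), and restricted to those 12 the median was -0.12 (percentile 0.85). The small RNA silencing machinery had -0.062 (percentile 10.2) and housekeeping genes -0.017 (percentile 42.9).

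Markers of other cell types were mostly dim on both arrays. Leukocyte markers had a median of -0.019 (percentile 18.7) and a mean of -0.062 (percentile 1.6), and the 1 member past the level filter was CD68, a lysosomal protein (363.7 and 237.5, -0.57). Endothelial markers had -0.019 (percentile 28.7), with 1 member, ENG, past the filter at -0.18. Epithelial markers had 0.042 (percentile 84.4), and of the 6 past the filter 3 were higher and 3 lower. Their leading members KRT8 and KRT18 are those of the epithelial-mesenchymal list, while CLDN4 (-0.26) and CLDN3 (-0.21) were lower.

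**Figure D3:**
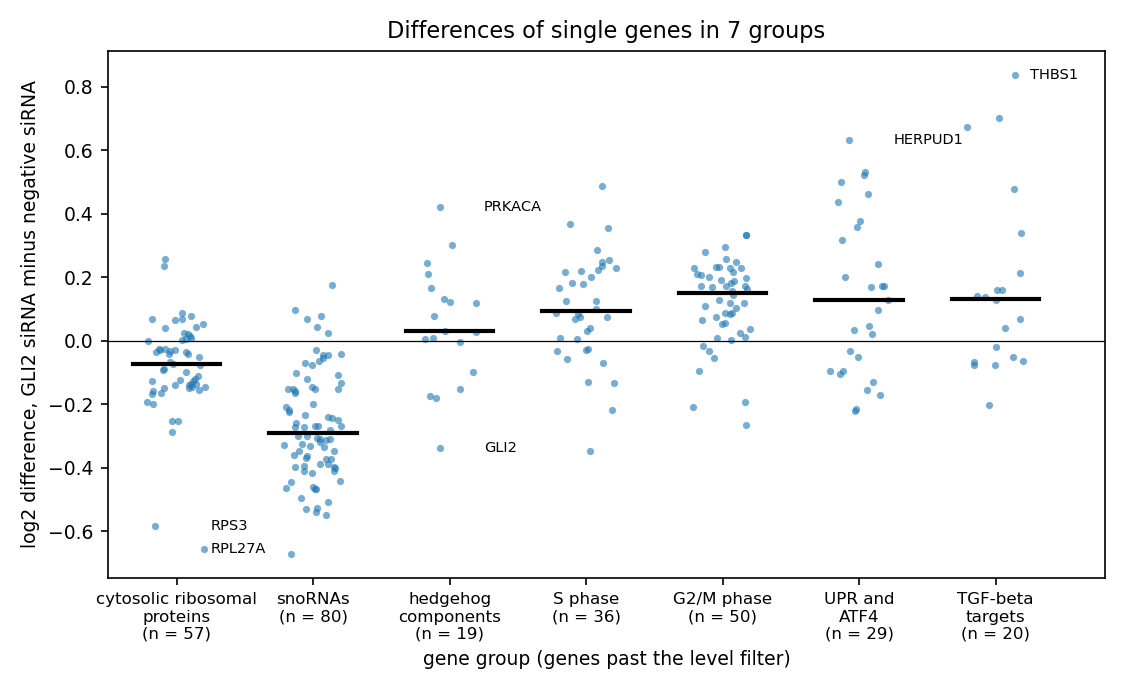
Each point is 1 gene past the level filter and the y axis its log2 difference, GLI2 siRNA minus negative siRNA; columns are 7 gene groups with their number of genes, and black bars are medians. Of 80 small nucleolar RNAs 74 lie below 0 (median -0.29), RPS3 and RPL27A lie apart from the other ribosomal protein genes, and most of the 50 G2/M genes lie above 0.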

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

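With 1 array per group no replicate could be left out and no paired or batch analysis exists. The log2 differences of GLI2 and RPS3 moved by less than the spread between probe sets of 1 gene under all 5 normalizations and pseudocounts tried. The ribosomal protein, epithelial-mesenchymal, S phase, G2/M, unfolded protein, cholesterol and TGF-beta lists stood apart under all 8 alternatives. Of these, the setting with nothing subtracted shifts a list and its random lists equally, so it could not change a percentile. The counts past 2-fold, 1 higher and 5 lower, were small and unstable. The higher count was 0 with no median subtracted, 3 at pseudocount 1 and 0 at pseudocount 64, where the lower count was 2. Both counts were 0 with the level filter at the 75th percentile and 0 at 3-fold, and at 1.5-fold they were 56 and 35. Without a level filter there were 1 and 7. TM4SF18 dropped under 2-fold with nothing subtracted. The list of reported GLI targets returned inside the central 95% in 7 alternatives: 0.065 under quantile normalization, 0.064 under loess, 0.069 at pseudocount 1, 0.039 at pseudocount 64, 0.059 with probe sets averaged, 0.072 for members past the filter and 0.060 for the mean. The Wnt list did so for members past the filter (0.0997) and for the mean (0.062). Under loess the invasion list moved to 0.027 and the integrin list to 0.045, and the integrin mean was 0.051. Restricted to members past the filter, the osteoblast median was 0.079, the interferon median -0.085, the endothelial value -0.18, the Notch median 0.16 (now standing apart) and the leukocyte value -0.57, which is CD68 alone. The leukocyte mean (-0.062) also stood apart. The NF-kB median changed sign to -0.12 past the filter, with a mean of -0.058 over all members. The hypoxia list stood apart only under quantile normalization (0.073). Apart from the lists restricted by construction to fewer genes, the cause was not tested. Of 500 values for the 100 other named genes, 3 changed sign, all of genes with a difference of 0.0086 or less. What limits all values is the number of arrays, and dim genes are compressed by the pseudocount.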

Other observations

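Gene groups in this part other than the fixed lists, and the tests of RPS3 against the other ribosomal proteins, of short RNAs and of histone genes, were chosen after the data were seen. So were the single genes named in this part that the naming rule does not cover. The loess correction was fixed beforehand, but its use as a test of these patterns was not. Insulin-like growth factor binding proteins, which bind and regulate these growth factors outside the cell, went both ways, with 4 of 6 measured members higher and 2 lower. The 3 past the level filter were higher, and the group was chosen after their values were seen. IGFBP5 had intensities of 442.4 and 890.8 (0.99), IGFBP7 1834.9 and 2930.6 (0.68) and IGFBP4 719.3 and 1111.0 (0.62). Other genes with large positive differences were the phosphatase PTP4A3 (175.0 and 355.2, 0.97), the glypican GPC4 (0.89), the small heat shock protein CRYAB (0.82) and the syndecan SDC2 (0.76). The mechanosensitive channel PIEZO2 was higher on each of its 3 probe sets, by 0.53, 0.79 and 0.90. On the lower side were the coagulation inhibitor TFPI (628.1 and 306.1, -0.99), DOCK4 (-0.93) and the glycosyltransferase B4GALT6 (1222.1 and 653.5, -0.88).

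Further genes with low values, picked for them and tested as no group, were SLAMF7 (338.0 and 204.8, -0.67), the interleukin-7 receptor IL7R (524.8 and 323.1, -0.66), CD22 (-0.62), LAMP3 (-0.61) and the inflammatory caspase CASP4 (603.1 and 398.4, -0.57). The fixed leukocyte list did not stand apart (median -0.019, with 7 of 16 above 0 after median subtraction). Those above 0 include CD3D, FCGR3A and MS4A1, whose intensities were equal on both arrays, and CD2 (34.5 and 34.3). The list's member PTPRC was dim on both arrays at 12.8 and 12.3, and TYROBP had 126.5 and 129.4. Collagen genes had a median of 0.00017 over 44 members, and mitochondrial ribosomal proteins had -0.025 over 74 (percentile 9.69). Keratins had -0.028 over 48 members (percentile 10.7), of which 5 passed the level filter. Of these KRT75 (0.74), KRT8 (0.69), KRT18 (0.35) and KRT14 (0.21) were higher and KRT80 (-0.29) was lower. Long noncoding RNAs had -0.012 over 631 genes (percentile 1.92). Across 8589 overlapping blocks of 30 neighbouring genes, the block medians ran from -0.14 to 0.16. They were not compared with random blocks, so whether any region was shifted was not tested.

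The lower level of RPS3 was compared with 3 explanations. A shared shift of ribosomal protein genes would place RPS3 among them. It lay at -0.58 while the 2.5th percentile of the other 60 was -0.27. RPS3 may have been picked for its low value on these same arrays. A gene so picked would lie low in its class whatever the cause, so no conclusion on a shared shift is drawn. RPS3 was not the lowest of its class, because RPL27A lay lower still at -0.66. A level-dependent trend between the arrays would vanish under the loess correction, which left RPS3 at -0.54. A difference between the 2 cultures unrelated to the siRNA remains open, because there is 1 array per group, from 1 culture or a pool, and an effect of GLI2 siRNA on RPS3 is open on the same grounds. Reads of RPS3 pseudogenes by the probes were not tested.

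Ribosomal protein genes and snoRNAs were lower together, snoRNAs by more. Over all levels 127 of 175 snoRNAs were lower (median -0.15), and past the level filter 74 of 80 were (median -0.29, and between -0.30 and -0.25 under the 5 normalizations and pseudocounts). Loss of host transcripts, from whose introns most snoRNAs are cut, was tested on 43 snoRNAs in 30 host genes. Hosts were lower too (median -0.093, percentile 0.73), but snoRNA and host differences did not track each other (r = 0.037, rho = 0.047, bootstrap interval over hosts -0.16 to 0.27, across genes that are not independent replicates). The snoRNAs lay below their hosts by a median of -0.20 (interval -0.28 to -0.042). The snoRNAs were examined as a class because they were low, so this gap partly restates the pattern. No conclusion on hosts as the cause is drawn from it. For the ribosomal protein genes, a level-dependent trend as the whole cause is argued against by the loess-corrected median of -0.073, against -0.089 uncorrected. That it stayed below the 2.5th percentile adds little, because the random lists were already matched on level. A lower yield of short RNAs in the GLI2 siRNA sample stays open for the snoRNA part: 16 of 23 other short RNAs were lower, but their median of -0.076 lay at percentile 2.45, within sampling error of the limit. Small nuclear RNAs at all levels go with it, with 17 of 20 lower and a median of -0.10 (percentile 0.13), though only 6 of them passed the level filter. If it were the source, the snoRNA difference may be one of RNA preparation. Whether such a difference would also lower ribosomal protein messengers was not tested.

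The upward shift of S and G2/M genes was not removed by the loess correction. The G2/M median was 0.14 with and without it, and the S phase median 0.11 with it and 0.093 without, so a level-dependent trend is an unlikely cause. The percentiles add little here, because the random lists were already matched on level and the correction could hardly change them. Replication-dependent histone genes, whose transcripts accumulate in S phase, were tested as a companion group. Of 56 measured genes 39 were higher, with a median of 0.067 (percentile 99.9), led by H1-1 (684.4 and 1068.6, 0.64). A slightly larger share of cycling cells in the GLI2 siRNA sample is a hypothesis that may account for these shifts, and the lower SLBP (-0.35) does not go with it. Cell counts by DNA content would test it and were not analysed here. Many histone genes are near-identical, so their probe sets are not independent. A difference between the 2 cultures unrelated to the siRNA, such as density at harvest, cannot be told apart from an effect of the siRNA with 1 array per group.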
